A study of Caenorhabditis elegans with 2 samples.

How the data were processed

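Chromatin immunoprecipitation and sequencing was done by the study's laboratory on whole late embryos of Caenorhabditis elegans that express ZTF-16 fused to GFP and FLAG, with an anti-GFP antibody and sonicated chromatin, per the labels. The 2 samples are biological replicates of 1 group, as the labels number them, so no groups were compared. The 8 deposited peak lists are in narrowPeak format, per the file notes deposited with them, in builds ce10 and ce11: a relaxed list for each replicate and for the pool, and the IDR-thresholded list. Each relaxed list was called by the authors against 1 control file, the same for both replicates, per the deposited notes. The aligner, the peak caller, the IDR threshold and the treatment of reads that map to several places are not given in the sources used here. A peak's signal value is the deposited output of the authors' caller, comparable only within its list. The deposited −log10 q-value shares one highest value over many peaks (849 of 14968 in the pooled ce11 list), so it was not used to rank peaks. The 822 IDR-thresholded peaks are the 822 pooled peaks with the highest signal. Most peaks of the ce11 IDR-thresholded and pooled lists are 440 bp wide with the summit at the centre, which limits the resolution of the positions. The median width in the other lists was 436 or 444 bp. No read numbers are in these lists, so depth is unknown.

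Positions were read as 1-based, and ce11 was the main build. Genes came from Ensembl release 115 on WBcel235, the same assembly as ce11, and sequences and tRNA isotypes from the RefSeq files of that assembly. No coordinates were converted between builds, and ce10 lists were used only for counts per list, per chromosome and between replicates. The 6 nuclear chromosomes and their 19973 protein-coding genes were used. Before the data were examined, the tests, the alternatives, 30 gene lists and the rule for named genes were written down. The rule names the gene with the nearest 5' end of the 15 strongest peaks, up to 4 targets with the highest signal of each list past the threshold and up to 2 of each other list, 6 genes related to ztf-16 (ztf-16, ehn-3, hbl-1, sdz-12, ver-1 and ttx-1) and the 5 6-mers with the lowest adjusted p. Names outside the rule (non-coding genes beside a peak, host genes, other 6-mers and the further zinc-finger and heterochronic genes in the closing part) were chosen after their values were seen.

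Replicate agreement was the share of the strongest 822 peaks of replicate 1 with a summit of the strongest 822 of replicate 2 within 200 bp, with a one-sided permutation test on 1000 circular shifts. A promoter window ran from 1000 bp upstream to 200 bp downstream of a 5' end. Promoter location and nearness to small non-coding genes (within 200 bp) were tested two-sided against 1000 random placements within chromosomes. Chromosome shares were tested by exact binomial tests, gene lists and location by signal by two-sided Fisher's exact tests, and 6-mers within 50 bp of the summit by an exact sign test against a flank centred 200 bp to one side, drawn at random. Adjustment was by Benjamini-Hochberg at a threshold of 0.05. Some listed names are non-coding or absent from the annotation and dropped out (members used are given with each list). The lists cover glia, somatic gonad, hypodermis, heterochronic, Hox, neuronal fate, pan-neuronal, cilia, muscle, pharynx, intestine, excretory system, germline, Wnt, Notch, TGF-beta, stress and cell cycle genes, genes related to ztf-16, and 11 families matched by name pattern.

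Alternatives varied the match distance, list length, build, window, signal range, background, k-mer length and control, and left out each replicate in turn by using the 822 strongest peaks of the other replicate alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The tests were run on simulated summits first, and the list test on genes drawn at random. A simulated promoter share of 60.7% over 822 summits was recovered as 60.1%, a simulated replicate agreement of 70.0% as 70.0%, a list with 20 added targets was found in 50 of 50 sets, and an added 6-mer ranked 1 among the enriched. Among 100 null sets, 7 had a promoter p and 7 an X chromosome p under 0.05, and 2 of 50 null sets gave any list past the threshold. The list sets drew each gene independently, so their rates do not cover target genes that share a summit.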

Results

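The data are lists of genomic sites at which ZTF-16, a C2H2 zinc-finger protein of Caenorhabditis elegans related to Hunchback and Ikaros, was recovered by chromatin immunoprecipitation and sequencing (ChIP-seq). The animals carried an integrated transgene that encodes ZTF-16 with GFP and FLAG at its carboxyl terminus, and the precipitation used an antibody against GFP. Whole late embryos of mixed sex were taken 5 hours after synchronisation by egg bleaching. The series holds 1 group with 2 biological replicates and no second condition, so the question the design implies is where the tagged protein was detected in both replicates. Each replicate, and both pooled, had a relaxed peak list meant as input to the irreproducible discovery rate (IDR) procedure, which weighs how alike peaks rank in replicates. The deposited name of the relaxed pooled list is peaks and background, so its weaker entries may be background and not sites. The IDR-thresholded list is the pooled peaks with the highest signal, so its members need not rank alike in both replicates. On assembly ce11 the relaxed lists held 21235 peaks for replicate 1, 18242 for replicate 2 and 14968 for the pool, and the IDR-thresholded list held 822. The deposited lists carry no read counts, so the depth of each library is unknown, and the intervals given are Wilson 95% intervals unless another kind is named, and cover counting error over peaks or genes only.

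Sites in the IDR-thresholded list lay largely at 2 kinds of gene, small non-coding RNA genes and the promoters of protein-coding genes. Of the 822 summits, 237 (28.8%) lay within 200 bp of an annotated tRNA, snoRNA, snRNA, rRNA or miRNA gene. Away from those genes, 410 of 585 summits (70.1%) fell in a promoter window, taken from 1000 bp upstream to 200 bp downstream of the 5' end of a protein-coding gene. The remaining 175 summits (21.3%) were in neither place. By gene structure, 568 summits (69.1%, interval 65.9 to 72.2) were intergenic with respect to protein-coding genes, 206 (25.06%) were intronic, 34 (4.14%) were in untranslated exon sequence and 14 (1.70%) in coding exons, where random positions on the same chromosomes gave 36.7%, 33.9%, 4.99% and 24.5%.

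The tRNA genes, transcribed by RNA polymerase III, were the largest small non-coding class. A tRNA gene lay within 200 bp of 165 summits, 20.1% (interval 17.5 to 22.9) against 0.295% for randomly placed summits, a 68.1-fold excess. For snoRNA genes, whose products guide modification of other RNAs, the count was 56 (6.81%, interval 5.28 to 8.74, 36.2-fold). For snRNA genes it was 11 (1.34%, 22.4-fold) and for miRNA genes 6 (0.730%, 5.94-fold). No summit lay near any of the 20 annotated nuclear rRNA genes. In a two-sided permutation test with 1000 placements, adjusted over the 5 classes, the adjusted p was 0.00333 for tRNA, snoRNA and snRNA genes, which rests on the smallest p the placements can give (0.002), 0.004995 for miRNA genes and 1 for rRNA genes. Seen from the genes, 169 of 612 nuclear tRNA genes (27.6%), 55 of 346 snoRNA genes (15.9%), 10 snRNA genes (7.75% of those annotated) and 6 of 261 miRNA genes (2.30%) had a summit within 200 bp. Among the other pooled peaks, which may include background, 1.34% were near a tRNA gene and 0.447% near a snoRNA gene. Both shares were lower than in the IDR-thresholded list by Fisher's exact test (adjusted p = 6.95e-114 and 2.00e-38). The miRNA excess did not pass among the upper 411 peaks by signal (adjusted p = 0.267 by the permutation test), and how reads shared by identical gene copies were treated is not given in the sources used here.

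**Figure D1:**
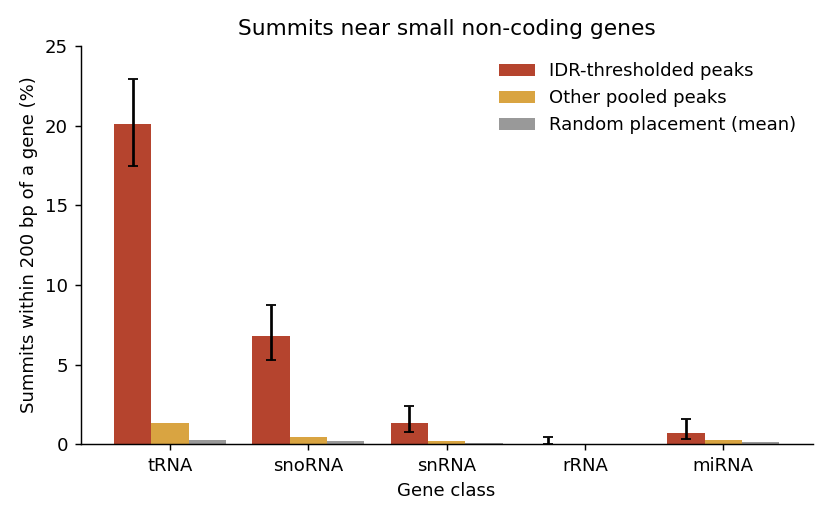
Share of summits within 200 bp of an annotated gene (y axis, percent) for 5 small non-coding gene classes (x axis), in the IDR-thresholded peaks (red, with Wilson 95% intervals), in the other pooled peaks (yellow) and as the mean of random placements (grey). The tRNA share of 20.1% compares with 1.34% in the other pooled peaks and 0.295% at random.

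The highest signals were also often at small non-coding genes, with the authors' signal value used here only to rank peaks within a list. Among the upper 411 peaks 38.4% were near a gene of the 5 classes, against 19.2% of the lower 411 (Fisher's exact test, two-sided, p = 1.47e-09). The median signal was 206 at snoRNA genes, 136 at snRNA genes, 124 at tRNA genes, 99.6 at miRNA genes (6 peaks) and 102 at peaks near none of the classes. Of the 15 strongest peaks, 7 had a snoRNA gene within 200 bp and 1 had the miRNA gene mir-51. The strongest, with signal 835, had its summit at III:8043961 (peak 8043795 to 8044154), in intergenic sequence 526 bp upstream of the 5' end of K12H4.5, and no gene of the 5 classes lay within 200 bp. The next, at V:12303634 (signal 619), lay in an intron of frm-7 beside the snoRNA genes C51F7.3 and C51F7.4, with F55C5.17 as the gene with the nearest 5' end. The nearest 5' ends to the other 5 of the 7 strongest were those of W03C9.1, sre-23, tasp-1, pxn-1, which encodes a peroxidasin, and ftt-2, which encodes a 14-3-3 protein. After these came str-56, rpl-3, T02E1.2, Y43F8C.7, hrg-5, ears-2, M01F1.9 and atx-2, the ataxin-2 gene. The summit lay inside the promoter window of the nearest gene for 9 of the 15, among them tasp-1 and atx-2 (each 56 bp upstream, at III:10759251 and III:10461333) and ears-2 (11 bp upstream, at IV:390479). All 15 ranked 20 or better in each replicate's own list.

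Promoter windows held 467 of the 822 summits, or 56.8% (interval 53.4 to 60.2), compared with 20.9% for random placement, a 2.71-fold excess (two-sided permutation p = 0.002, the smallest that 1000 placements can give). The other pooled peaks, which may include background, had 27.5% of 14088 summits in such windows (Fisher's exact test, p = 5.27e-65). Summits in the window lay a median of 211 bp upstream of the nearest 5' end. The windows assigned summits to 658 of 19973 protein-coding genes (3.29%), and 186 of the 467 summits served 2 or more genes. The promoter share was 56.9% in the upper 411 peaks by signal and 56.7% in the lower 411, a difference that did not pass the threshold (Fisher's exact test, p = 1). Without the peaks near small non-coding genes, a restriction chosen after the data were seen, the shares were 75.3% in the upper and 64.7% in the lower 292 peaks (Fisher's exact test, p = 0.00664).

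Ribosomal protein genes and histone genes were over-represented among these target genes, and chemoreceptor genes were under-represented. No peak list from animals without ZTF-16-GFP was analysed, so whether these differences are particular to ZTF-16 was not tested. Of 76 cytosolic ribosomal protein genes 25 were targets, 32.9% (interval 23.4 to 44.1) against 3.29% of all protein-coding genes, which is 9.98-fold (Fisher's exact test, two-sided, adjusted p = 2.73e-17 over 30 lists). The name pattern leaves out names that end in a letter, such as rpl-7A, itself a target (signal 124). The list's fold was lower, and still past the threshold by Fisher's exact test, with nearest 5' ends alone (13 of 76, 4.44-fold, adjusted p = 8.99e-05) and against genes with a relaxed pooled peak in the window (25 of 64, 2.78-fold, adjusted p = 1.33e-05). Over all alternatives with Fisher's exact test the adjusted p ran from 7.02e-18 to 8.99e-05. Against random lists matched on the distance to the upstream gene it was 6.70-fold (permutation test, adjusted p = 0.0030, resting on the smallest p those lists can give). The highest signals among them were at rpl-3 (409, summit III:3867584, 270 bp upstream of the 5' end), rpl-15 (308, IV:654916, 340 bp upstream), rpl-20 (277, IV:4750067, 289 bp upstream) and rps-1 (234, III:4475672, 246 bp upstream), all intergenic. Of 72 histone genes 11 were targets (15.3%, interval 8.75 to 25.3, 4.64-fold, adjusted p = 2.22e-04 by Fisher's exact test). These 11 genes rested on 6 summits, since 10 of them shared a summit with a neighbouring histone gene, and the test and interval treat them as independent. A summit at I:9988972 with signal 308 lay between his-67 and his-68, 209 and 160 bp upstream of their 5' ends, and the next in signal were his-37 (141, V:9546975) and his-31 (128.7, IV:8334192). The histone list did not pass without replicate 2 (3.03-fold, adjusted p = 0.0824 by Fisher's exact test), in the upper 411 peaks (4.15-fold, adjusted p = 0.0542) or when each summit went to its nearest 5' end alone (2.16-fold, adjusted p = 0.237). Over all alternatives its adjusted p ran from 1.90e-05 to 0.237. Histone genes occur as near-identical copies, to which short reads cannot always be assigned. Of 1171 chemoreceptor-like genes of the sr families 6 were targets (0.512%, 0.156-fold, adjusted p = 8.15e-10 by Fisher's exact test). The strongest were sre-23 (520, I:8259569, beside the snoRNA gene ZK265.10), sre-1 (234, II:7708777), sri-5 (170, I:11182555) and srh-269 (94.7, V:16592278, near a tRNA-Gln gene). With only genes that had a relaxed pooled peak in the window as background, the sr list did not pass (6 of 89 genes, 0.480-fold, adjusted p = 0.334 by Fisher's exact test, the highest over the alternatives, where the lowest was 2.76e-11).

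**Figure D2:**
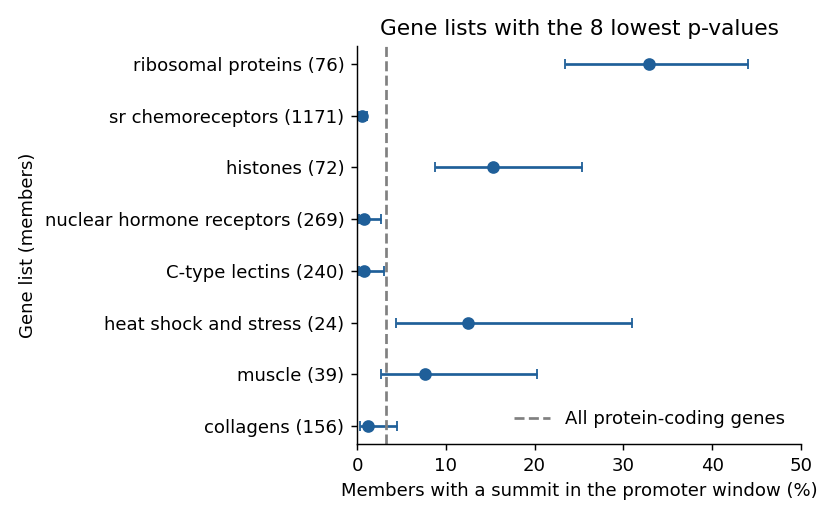
Share of list members with an IDR-thresholded summit in the promoter window (x axis, percent, points with Wilson 95% intervals) for the 8 lists with the lowest p-values (y axis, number of members in brackets), with the share over all protein-coding genes as a dashed line. Ribosomal protein genes stand at 32.9% and histone genes at 15.3%, and sr chemoreceptor genes at 0.512%, against 3.29% overall.

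The other 27 lists did not pass the threshold. Of 24 heat shock and stress genes 3 were targets (3.79-fold, p = 0.0431, adjusted p = 0.215 by Fisher's exact test), with hsp-60, a mitochondrial chaperonin gene (signal 204, III:1619126), and hsp-1, a cytosolic Hsp70-family gene (203, IV:17278597), the strongest. Without replicate 1 this list passed (4 of 24, 5.24-fold, adjusted p = 0.0486 by Fisher's exact test), and its adjusted p in the other alternatives ran from 0.0542 to 0.535. The counts were 3 of 39 for muscle genes, where unc-60 and unc-112 had signals of 93.3 and 85.5, 2 of 31 for Wnt pathway genes (mom-1 with 229 and vang-1 with 78.5) and 2 of 33 for cilia genes (daf-19, the RFX factor of ciliated neurons, with 97.9 and dyf-3 with 90.8). They were 2 of 269 for nuclear hormone receptors (nhr-255 with 227 and nhr-142 with 120), 2 of 240 for C-type lectins (clec-53 with 123 and clec-126 with 103.9), 2 of 156 for collagens (col-185 with 145 and col-71 with 107) and 2 of 140 for neuropeptide genes (flp-23 with 111 and ins-39 with 105). The summits assigned to mom-1, nhr-255, clec-126, col-185 and flp-23 lay within 200 bp of a tRNA gene. Ranks in replicates 1 and 2 were far apart at some of these targets, such as unc-112 (3265 and 484), daf-19 (1310 and 230) and vang-1 (692 and 1549). They were close at others, such as unc-60 (598 and 517). The nuclear hormone receptors, 0.226-fold with an adjusted p of 0.107 by Fisher's exact test, passed as under-represented with a 2000 bp window (0.260-fold, adjusted p = 0.0425) and without peaks near small non-coding genes (0.125-fold, adjusted p = 0.0421), and in the other alternatives the adjusted p ran from 0.128 to 1. A single target was found among 34 cell cycle genes (lin-35, the Retinoblastoma homologue, signal 290 at I:5807465), 42 germline genes (mex-1, 199.8), 15 heterochronic genes (lin-66, 100.8), 18 excretory system genes (vha-8, 103.95), 25 genes named ztf (ztf-3, 83.5) and 33 proteasome genes (rpn-7, 108). The heterochronic and ztf lists passed only when each summit went to its nearest 5' end (adjusted p = 0.0159 and 0.00302 by Fisher's exact test). No target was found in 13 lists, namely 63 ceh homeobox genes, 46 neuronal fate genes, 40 intestinal, 34 hypodermal and seam, 31 pharyngeal, 25 pan-neuronal, 25 hlh, 24 glial, 23 Notch pathway, 20 TGF-beta pathway, 16 somatic gonad and 15 Hox and posterior patterning genes, and the 6 genes related to ztf-16. With 3.29% of all genes as targets, 0 of 24 glial genes still allows a share of up to 13.8% (Wilson upper bound), so lists of this size could not show a deficit.

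None of the 6 genes chosen in advance for their relation to ztf-16 had an IDR-thresholded summit in its promoter window, and 1 of them, ztf-16, had one with a 2000 bp window. The ztf-16 gene itself (X:4805998 to 4811540, minus strand) had 2 such summits in its introns, the nearer at X:4810283 (signal 125, rank 303) and 1257 bp downstream of the 5' end, and an intergenic one 1873 bp upstream, at X:4813413 (signal 118, rank 333). The relaxed pooled list held 2 peaks in the promoter window of ztf-16, the stronger with signal 49.04 and rank 2652. That peak had rank 1078 in replicate 1 and no rank in replicate 2. The transgene carries ztf-16 and may add copies of this locus. For hbl-1, a Hunchback-like gene (X:5822142 to 5827755), the nearest IDR-thresholded summit was 9922 bp upstream, and the strongest relaxed pooled peak in its window had signal 49.7. That peak had rank 12182 in replicate 1 and 1880 in replicate 2. For ver-1 (III:156824 to 163542) a relaxed pooled peak with signal 30.6 and rank 12215 lay 72 bp downstream of the 5' end. That signal is close to the lowest in the relaxed pooled list (28.4), so the peak may be background. No relaxed pooled peak was in the window of ehn-3 (IV:5416699 to 5419222), sdz-12 (II:3730152 to 3731823) or ttx-1 (V:20053719 to 20064176), and their nearest IDR-thresholded summits were 48137, 164033 and 341097 bp away.

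Peaks were not distributed over chromosomes as protein-coding genes are. The X chromosome held 176 of 822 peaks (21.4% against 13.7% of genes, 1.57-fold, adjusted p = 4.87e-09), chromosome III 150 (18.2% against 13.2%, adjusted p = 9.03e-05) and chromosome I 146 (17.8% against 14.4%, adjusted p = 0.0109), by exact binomial tests adjusted over 6 chromosomes. Against its share of chromosome length (17.7%) the X excess was smaller, 1.21-fold (adjusted p = 0.0121 by the exact test). Chromosome V held 13.6% of peaks against 25.004% of genes (0.545-fold, adjusted p = 7.74e-15 by the exact test) and chromosome II 14.5% against 17.3% (adjusted p = 0.0405 by the exact test). The whole relaxed pooled list, which may include background, had similar shares on chromosomes I (18.19%) and III (18.57%). The excess on I and III was therefore not particular to the IDR-thresholded peaks. Chromosome V was also below its share of genes there (16.66%), while X held less than among the IDR-thresholded peaks (15.49%). These differences between lists were not tested. The chromosome II deficit passed again only with the ce10 list (adjusted p = 0.0257 by the exact test), and in the other 6 alternatives, leaving out either replicate among them, its adjusted p ran from 0.0587 to 0.612. The chromosome I excess did not pass in the upper 411 peaks (1.10-fold, adjusted p = 0.400 by the exact test), and its adjusted p elsewhere ran from 3.76e-04 to 0.0431. Chromosome IV, with 14.5% of peaks against 16.43% of genes, did not pass (adjusted p = 0.144 by the exact test), but did against its share of chromosome length (0.830-fold, adjusted p = 0.0364 by the exact test, with 0.146 to 0.363 in the other alternatives). The X chromosome carries 276 of the 612 nuclear tRNA genes, and 78 of its 176 peaks lay near one. Without peaks near tRNA genes, a restriction chosen after the data were seen, X held 98 of 657 peaks (14.9%, 1.09-fold) and did not pass (adjusted p = 0.363 by the exact test, the highest over the alternatives, where the lowest was 2.24e-09). Without peaks near any of the 5 small non-coding classes X held 97 of 585 (16.6%, 1.21-fold) and did not pass after adjustment either (p = 0.0468, adjusted p = 0.0587 by the exact test).

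**Figure D3:**
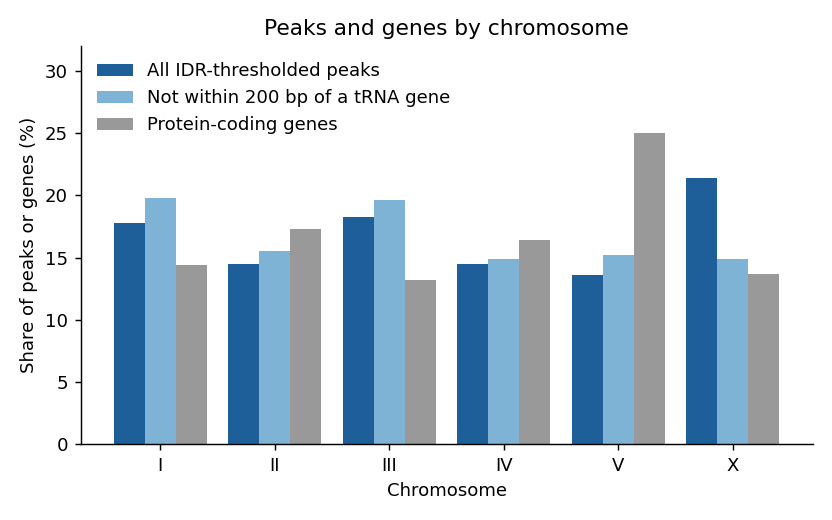
Share (y axis, percent) of all IDR-thresholded peaks (dark blue), of peaks not within 200 bp of a tRNA gene (light blue) and of protein-coding genes (grey) on each nuclear chromosome (x axis). On X the share of peaks is 21.4% with and 14.9% without those near tRNA genes, and 13.7% of genes are there.

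Sequences around the summits were rich in G and C. Windows reaching 50 bp to either side of the 822 summits had a GC content of 48.8% ± 8.07 (SD over peaks), against 37.05% ± 9.71 in windows 200 bp to one side of the same summits. Of all 6-mers, each counted with its reverse complement, 386 were enriched at summits over flanks and 295 were depleted (exact sign test, adjusted p under the threshold of 0.05). The enriched set held 222 6-mers with a CG step (57.5%), compared with 29.0% of all 6-mers. The 5 lowest adjusted p-values, from the exact sign test, belonged to AAAATT (in 16.42% of summit windows and 39.2% of flanks, adjusted p = 1.99e-22), CGCGCA (14.7% and 1.70%, adjusted p = 7.63e-20), AAAAAT (25.06% and 47.3%, adjusted p = 1.85e-19), TAAAAA (12.8% and 31.8%, adjusted p = 3.49e-18) and GCGCAC (14.96% and 2.56%, adjusted p = 2.05e-17). Against windows of other pooled peaks matched on GC content, chosen as a control after the data were seen, CGCGCA (14.7% against 7.18%, adjusted p = 1.29e-04) and GCGCAC (14.96% against 5.11%, adjusted p = 4.63e-08) stayed enriched by Fisher's exact test, and AAAATT, AAAAAT and TAAAAA did not differ past the threshold (adjusted p = 0.491, 0.552 and 0.908 by Fisher's exact test).

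The replicates shared most of their strongest peaks. Of the 822 highest-signal peaks of replicate 1, 558 (67.9%) had one of the 822 highest of replicate 2 within 200 bp, against a mean of 0.350% over 1000 circular shifts (one-sided permutation p = 0.001, the smallest the shifts can give). Over these 558 pairs the signals of both replicates had a Spearman correlation of 0.718, across peaks, which are not independent replicates. The share fell with the length of the lists, from 79.0% for the 100 strongest peaks to 31.1% when all peaks of both lists were used. Of the IDR-thresholded summits, 818 had a summit of both full replicate lists within 200 bp, and 561 had one among the 822 strongest of both. Both replicates were called against the same control file, so part of the shared peaks may come from that control.

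**Figure D4:**
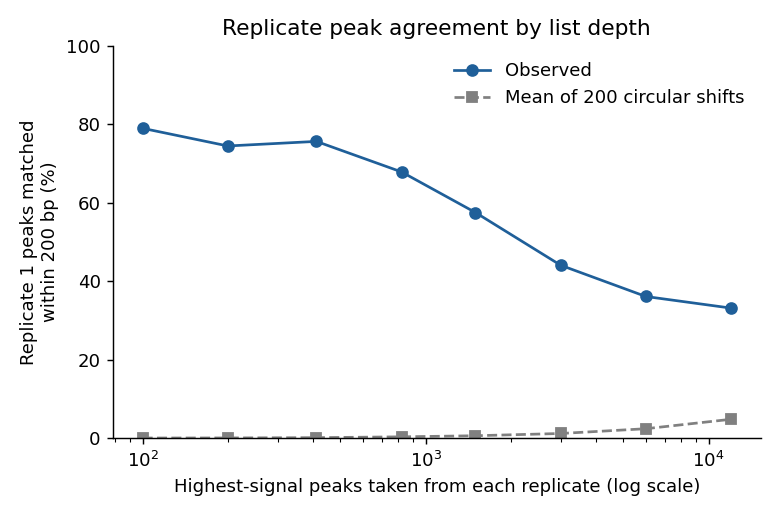
Share of replicate 1 peaks with a replicate 2 summit within 200 bp (y axis, percent) when the same number of highest-signal peaks is taken from each list (x axis, log scale), as observed (blue circles) and as the mean of 200 circular shifts (grey squares). The observed share is 79.0% for 100 peaks and 67.9% for 822 peaks.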

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

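The restrictions to peaks away from small non-coding or tRNA genes, the GC-matched control and the comparison of non-coding shares with other pooled peaks were chosen after the data were seen. Over 223 recomputed values, 180 kept their direction and their side of the threshold, or for counts stayed within 1.5 times. Replicate agreement, IDR peak count and promoter share kept theirs under each alternative run, with agreement between 31.1% and 75.7% and promoter share between 47.4% and 70.1%. The number of chromosomes past the threshold was 5, and 3 in the upper 411 peaks, without peaks near small non-coding genes and without peaks near tRNA genes, and 4 with either replicate left out. Target genes were 334 in the upper 411 peaks, by construction. Over-represented lists were 2, and 1 in the upper 411 peaks, 3 with nearest 5' ends and 1 to 3 with a replicate left out (1 without replicate 2, 3 without replicate 1). Enriched 6-mers were 386, and 231 with 25 bp windows, 220 in the upper 411 peaks (fewer peaks), 249 without peaks near small non-coding genes and 97 with GC-matched windows. The promoter difference between stronger and weaker peaks was 0.243 percentage points, -1.46 between the 205 strongest and 205 weakest peaks, -1.46 with a 500 bp window, -0.973 to -0.243 with a replicate left out, none past the threshold, and 10.6 without peaks near small non-coding genes. The ztf list, 1.21-fold, was 0-fold in the upper 411 peaks and 0.594-fold against genes with a relaxed peak. The heterochronic list, 2.02-fold, was 0-fold in the upper 411 peaks, 0.891-fold against genes with a relaxed peak and 0 to 2.08-fold with a replicate left out. With GC-matched windows, AAAAAT and TAAAAA were 2.68 and 0.852 percentage points more frequent at summits than in the control. Except where stated, the cause was not tested. No paired analysis was possible because there is 1 group. Depth is unknown, so it could not be weighed.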

Other observations

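The tests on peaks away from tRNA and small non-coding genes, on X against autosomal tRNA genes, on both replicates' tRNA shares, on single-copy tRNA genes and on isotypes were chosen after the results they concern were seen. At tRNA genes the summit lay a median of 21 bp downstream of the tRNA 5' end (quartiles 2 and 62, 165 summits) and inside a tRNA gene for 100 of 165. The share of genes with a summit ran from 38.2% (13 of 34 tRNA-Thr genes) to 18.5% (5 of 27 tRNA-Gln genes) among isotypes with more than 1 gene, and none of 21 isotypes passed Fisher's exact test (adjusted p = 1 for each). In summit windows near tRNA genes the 6-mer CGAACC, whose reverse complement GGTTCG belongs to the conserved B box of the internal tRNA promoter, was found in 40.6% against 4.24% of flanks (adjusted p = 4.61e-11, exact sign test). These windows were picked for nearness to tRNA genes, and 100 of their 165 summits lay inside one. Enrichment of tRNA gene sequence was thus set by the selection and is no evidence on what was bound.

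Several genes of the ztf and heterochronic lists had IDR-thresholded peaks outside the promoter window. When each summit went to its nearest 5' end, 6 of 25 ztf genes (6.23-fold, adjusted p = 0.00302, Fisher's exact test) and 4 of 15 heterochronic genes (6.93-fold, adjusted p = 0.0159, Fisher's exact test) had one. The ztf genes were ztf-16, ztf-6, ztf-27, ztf-22, ztf-1 and ztf-3, and the heterochronic ones lin-66, lin-42 (2 intronic summits, at II:1242632 and II:1247010), kin-20 (intronic, X:15275605) and lin-28 (intronic, I:8410020). The ztf-22 and ztf-1 summits lay in introns of other genes, Y48C3A.5 and zfp-1, 5781 and 2605 bp upstream. The ztf-6 summit was intergenic and 4490 bp upstream. The ztf count also includes ztf-16, the gene carried by the transgene. Long genes and wide intergenic regions collect more nearest summits, which was not tested.

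The excess of peaks on X may follow in part from where tRNA genes lie, since away from them X held 14.92% of peaks (exact 95% interval 12.28 to 17.87), which includes its 13.7% share of protein-coding genes, although without peaks near any small non-coding gene it held 16.6% (p = 0.0468, adjusted p = 0.0587, exact binomial test). Around ztf-16 itself, of which the transgene may add copies, 5 peaks lay within 50 kb, where the mean density over the genome gives 0.865. These 5 of the 176 X peaks are too few to make up the excess, and without them X still held 20.93% (exact binomial p = 1.31e-08). That p largely restates the X excess, since removing so few peaks could hardly change it. X tRNA genes were not occupied detectably more often than autosomal ones (79 of 276 against 90 of 336, odds ratio 1.096, 95% interval 0.756 to 1.59, Fisher's exact p = 0.650). No biological explanation was tested, since the design has 1 group.

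Peaks at tRNA genes were in both replicates, with 18.2% and 19.3% of each one's 822 strongest peaks, a ratio of 1.06, which argues against a single replicate as their source. Reads shared evenly between identical copies would mark every copy, but of 45 families of identical tRNA sequence with an IDR-thresholded summit 42 (93.33%) also held a copy without one. A copy without one may still carry a weaker relaxed peak, since 1.34% of the other pooled peaks were near a tRNA gene. Genes in families of identical copies also had a summit more often than single-copy genes (144 of 469 against 25 of 143, Fisher's exact p = 0.00188), so some sharing is not excluded. Recovery of highly transcribed chromatin in any anti-GFP precipitation remains open, since no peak list from animals without ZTF-16-GFP was analysed here. The same limit holds for the peaks at snoRNA, ribosomal protein and histone genes.

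The CG-containing 6-mers at summits do not come from small non-coding genes alone: 249 6-mers were enriched without the peaks near those genes, 156 of them with a CG step, and 149 of the 222 CG-containing 6-mers of the full set stayed among them. GC content may account for part of the pattern. Against GC-matched windows of other pooled peaks 97 6-mers were enriched, 64 of them with a CG step, a number between the limits of 10 and 100 set beforehand for GC content as the cause and not as the cause. This comparison kept the peaks near small non-coding genes. Among its lowest p-values was GTTCGA (12.8% against 4.87%, adjusted p = 1.10e-05, Fisher's exact test), found in 40.6% of summit windows near tRNA genes. CGCGCA and GCGCAC, also enriched there, were in 14.72% and 14.96% of all summit windows. Away from small non-coding genes their shares were higher, 18.46% and 17.78%. This argues against tRNA gene sequence as the source of these 6-mers. For the 97 6-mers as a set, the remaining share cannot be told apart from tRNA gene sequence, since those peaks were kept. Nor can it be told apart from differences in promoter type between the peaks and their matched windows, which were not matched.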
